A study of Mus musculus with 4 samples.

How the data were processed

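RNA levels in the neocortex of mouse embryos were measured on 4 two-colour arrays, each with RNA of a null mutant sample in one channel and RNA of a control pool in the other. Per the labels, the null samples are biological replicates, the pool was made from 4 control replicates, and total RNA of embryonic day 16 was used. Per the labels, null RNA was in Cy3 on 1 array and in Cy5 on 3 arrays. The source name of replicate 1 gives day 14, while its title and characteristics give day 16. It was kept as day 16.

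The values were the authors' processed log ratios, a single column per array, and 0 further columns of values were left unused. The deposited values were taken as log2 because they were centred near 0 and reached sizes too large for log10 ratios of a scanner. The log base, the background correction, the normalization and the numerator of the ratio are not given in the sources used here. Scanner intensities were not used here, so signal over background and saturation are unknown, and a strong compression or expansion of ratios by those steps would pass unseen. The column medians lay between -0.031 and 0.0044. For arrays, their number limits the precision.

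Of 6856 probes, 981 had no value on any array and 188 on some arrays only. The platform annotation gave a single gene symbol for 6269 probes, several for 6 and none for 581. Entrez IDs of 6250 probes were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Probes with several symbols or none were kept in the tests and not named, apart from a pair of probe IDs. No coordinates were used, because no genome build is named for the probes. Among the 5720 probes measured on replicates 2 to 4, 472 had no symbol.

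The choices that follow were made before the data were examined, unless stated otherwise. A rule that was to settle the direction of the ratios could not be applied, and the item it rests on is not reported here. As laid down for that case, the 3 arrays with null RNA in Cy5 gave the leading result, without a direction in terms of genotype. The fit of 4 arrays was run with replicate 1 turned, which is an assumption, and with replicate 1 as deposited. Mean log ratios were tested against 0 per probe with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over probes with a value on every array of the fit. P-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. All tests were two-sided. Dye and genotype cannot be told apart within the 3 arrays.

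The genes named were chosen as follows. Up to 12 genes per sign were to be named among those past the threshold with a single sign on every array. Where fewer than 5 passed, the 5 with the smallest p per sign and a single sign on every array were named as not passing. For each list, up to 4 members with the smallest p were added. The rule was also applied to both fits of 4 arrays, an extension made after the data were examined. Where several probes had the same symbol, the probe with the smallest p stood for the gene. Pou3f2, Pou3f3, Sox3, Xist, Uty, Kdm5d, Eif2s3y and Zfy1 were chosen for the closing observations, and Tal1 for a count of 1, after their values were seen.

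The 20 gene lists covered neuropeptides, dense core vesicles, presynaptic release, postsynaptic receptors, activity-regulated genes, neural progenitors, the cell cycle, projection neurons, interneurons, glia, cell stress and death, blood, vessels, meninges and mesenchyme, microglia and leukocytes, choroid plexus, striatum, diencephalon and hypothalamus, ribosomal proteins and the respiratory chain. Probes were averaged by symbol, which left 5051 genes on replicates 2 to 4. Of these, 456 were in a list and 11 in several. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. The lists hold textbook markers, and many marker genes of other tissues are also expressed at lower levels in the neocortex.

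The steps were tested on simulated data drawn from the variance prior of each fit, with 200 changed probes in each of 20 rounds. For 3 arrays (5720 probes), 54.6% of 2-fold and 96.6% of 4-fold changes were recovered, and 4.88% of calls were false. For 4 arrays (5687 probes), the shares were 74.3%, 97.5% and 3.81%. A shift of 0.3 of the neuropeptide list was called in 80% of rounds for 3 arrays and in 90% for 4 arrays. Of the list tests, only camera at the preset correlation was simulated. The simulated values were independent between probes, and each probe had the same variance on every array. These rates therefore do not cover correlated genes or arrays of unequal spread, and the real arrays had an SD of 0.40 to 0.63.

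Alternatives were the sign of replicate 1, a dye term, median centring, a common scale, a missing value allowed, averaging by gene, a robust variance prior, array weights, an adjusted p of 0.1, leaving out probes beyond 4 in size, other list tests and leaving out each replicate. The labels of 1 group cannot be permuted, so signs of whole arrays were flipped instead. Intervals of covariances between arrays came from 1000 bootstrap draws of probes, which are not independent, and were added after the data were examined. With 3 arrays, sign flips cannot give an exact two-sided p under 0.25, and with 4 arrays none under 0.125.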

Results

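RNA from the neocortex of mouse embryos at embryonic day 16 was compared between null mutants, whose brain the labels describe as synaptically silent, and a pool of control RNA. The question named by the series title is which genes are regulated by synaptic activity. Each of 4 two-colour arrays held RNA of a separate null sample, labelled as a biological replicate, beside the same pool of 4 control replicates. On replicate 1 the null RNA carried the dye Cy3, and on replicates 2, 3 and 4 it carried Cy5. The source name of the null sample on replicate 1 gives embryonic day 14, whereas its title and characteristics give day 16.

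The values were log ratios of both channels, taken as log2. Their numerator was not given in the sources used here, so that a positive value cannot be read as higher or lower in the null. Signs are therefore given as deposited. Replicates 2 to 4 ran the same way whichever channel was the numerator, and they carried the comparison. Because all arrays share a single pool, the pool counts as 1 control sample, and tests of the ratio against 0 leave out the spread between controls.

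Between 5777 and 5873 of the 6856 probes had a value on each array. The median log ratio was 0.0017 on replicate 1, -0.031 on replicate 2, -0.0034 on replicate 3 and 0.0044 on replicate 4. The SD over probes was 0.48 on replicate 1, 0.43 on replicate 2, 0.63 on replicate 3 and 0.40 on replicate 4. Replicate 3 had 7.82% of its probes beyond 1 in size, against 3.97% on replicate 1, 2.73% on replicate 2 and 1.70% on replicate 4. Gapdh, a glycolytic enzyme spotted 78 times, had a median between -0.08 and 0.05, with an SD between spots of 0.09 to 0.20. Across the 5687 probes measured on every array, Pearson's r was 0.24 between replicates 2 and 3, 0.23 between replicates 2 and 4, and -0.0022 between replicates 3 and 4. Replicate 1 had r of -0.02, 0.08 and -0.12 with replicates 2, 3 and 4. These are correlations across probes, which are not independent replicates.

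On replicates 2 to 4, no gene passed the adjusted threshold. Among named genes, the smallest p belonged to Smcp, a cysteine-rich protein of sperm mitochondria, with a mean log ratio of 1.44 ± 0.17 (SD, n = 3), which is 2.72-fold in size. The others with the smallest p on the positive side were Cdc42ep5, an effector of the GTPase Cdc42, at 1.00 ± 0.35, Casp8ap2, a protein of histone mRNA processing, at 0.98 ± 0.22, the axon guidance ligand Slit2 at 0.86 ± 0.16, and Enc1, a kelch protein of the nervous system, at 0.85 ± 0.11. On the negative side stood Ptgds, the prostaglandin D synthase abundant in the meninges, at -1.36 ± 0.62, and Sypl2, a relative of synaptophysin, at -1.32 ± 0.51. Car8, a carbonic anhydrase-related protein that binds the IP3 receptor, had -1.30 ± 0.36, Aass, an enzyme of lysine breakdown, had -0.83 ± 0.19, and the transcriptional repressor Bcl6b had -0.75 ± 0.12.

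Of 5720 probes tested with limma, 0 had an adjusted p under 0.05. The smallest adjusted p was 0.0788, for a probe without a gene name here (ID 2965), at 2.57 ± 0.38 (SD, n = 3). Another unnamed probe (ID 2996) had -1.81 ± 0.29 and an adjusted p of 0.146 with limma, Smcp had 0.167, and the other 9 named genes had 0.450. At an unadjusted p under 0.05, limma listed 553 probes, 321 positive and 232 negative, where 286 would be listed by chance with no effect. A single sign on all 3 arrays was seen for 1919 probes, or 33.5%, against 25% by chance, and 54 probes had a mean beyond 1 in size. These chance rates take the arrays as independent, whereas the 3 arrays share a pool and a dye orientation. The 95% interval of the median probe reached 0.41 to either side of its mean, or 1.33-fold.

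Weights for each array raised the number past the adjusted threshold to 3, namely Smcp and both unnamed probes, and the number at an unadjusted p under 0.05 to 1067. Without replicate 2 that unadjusted number was 236.

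**Figure D1:**
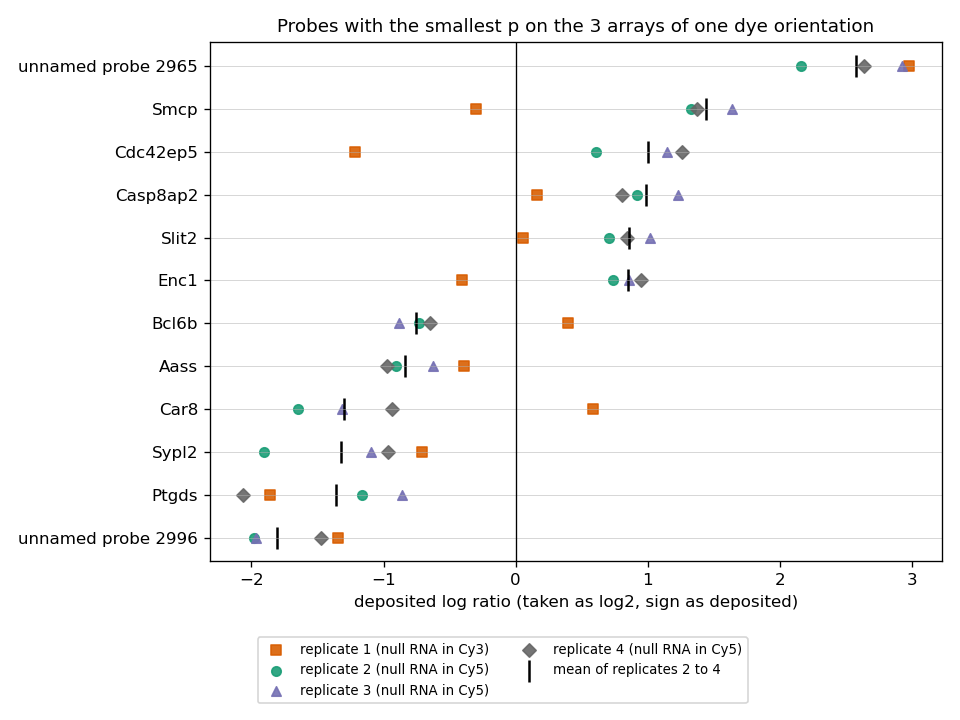
Deposited log ratio, taken as log2, on each of the 4 arrays (markers) and its mean over replicates 2 to 4 (bars) for the probes with the smallest limma p on replicates 2 to 4 and a single sign there. Smcp lies between 1.33 and 1.64 on replicates 2 to 4 and at -0.30 on replicate 1, while the unnamed probe 2965 lies between 2.16 and 2.98 on all 4 arrays.

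The 20 gene lists were fixed for neuronal and developmental genes, for cell metabolism and for other cell types the dissection could hold. On replicates 2 to 4, limma's camera with a preset correlation of 0.01 set 4 of them apart from the other genes. The ribosomal protein genes, which encode the parts of the translation machinery, had a mean of 0.16 with 31 of 39 members positive, and the neuropeptide genes a mean of 0.21 with 13 of 16 positive. The list of microglia and leukocyte markers had a mean of 0.22 with 10 of 15 positive. Genes of presynaptic release, the machinery of transmitter exocytosis, had a mean of -0.20 with 24 of 29 negative. Only measured members count here. These were 29 of 52 for presynaptic release, 16 of 39 for neuropeptides and 15 of 29 for microglia and leukocytes. The adjusted p from limma's camera with a preset correlation of 0.01 was 0.0138 for ribosomal proteins and for presynaptic release, and 0.0429 for neuropeptides and for microglia and leukocytes. With an estimated correlation none of the 4 calls held, with an adjusted p = 0.813 for ribosomal proteins, presynaptic release and neuropeptides and an adjusted p = 0.652 for microglia and leukocytes. That form of camera takes its degrees of freedom from the arrays, and 3 arrays leave few. Its smallest unadjusted p over the 20 lists was 0.107, so that it could hardly keep a call. None of the 4 lists passed with fry, which asks whether members move together and not whether they differ from the other genes. Its adjusted p was 0.547 for neuropeptides and presynaptic release, 0.0884 for microglia and leukocytes and 0.733 for ribosomal proteins.

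Presynaptic release held 6 members at an unadjusted p under 0.05, all negative. They included Syn3, a synapsin that coats synaptic vesicles, at -0.68 ± 0.32 (SD, n = 3), the membrane-bending protein Bin1 at -0.52 ± 0.24, Bsn, the active zone scaffold bassoon, at -0.45 ± 0.15, and Dnm1, the dynamin of vesicle recycling, at -0.74 ± 0.64. The list mean was -0.26 on replicate 2, -0.33 on replicate 3 and -0.0042 on replicate 4, with -0.21 on replicate 1. Without replicate 3 its adjusted p from camera was 0.274.

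In the neuropeptide list, 3 members were at an unadjusted p under 0.05, all positive. Ghrh, the growth hormone-releasing hormone, had 0.83 ± 0.57 (SD, n = 3), Npff, the neuropeptide FF precursor, had 0.38 ± 0.14, and Adcyap1, which encodes PACAP, had 0.54 ± 0.46. Npy, a peptide of cortical interneurons, had 0.31 ± 0.10 and missed that mark. The list mean was -0.04 on replicate 2, 0.26 on replicate 3 and 0.41 on replicate 4, with -0.41 on replicate 1. Its adjusted p from camera was 0.156 without replicate 3 and 0.301 without replicate 4.

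The microglia and leukocyte list held 5 members at an unadjusted p under 0.05, all positive. When p was adjusted over the list alone, Lyz1 and Laptm5 passed, which made 2 members against 0 over all genes tested. Lyz1, a lysozyme, had 0.74 ± 0.03 (SD, n = 3), Laptm5, a lysosomal membrane protein of blood cells, had 0.87 ± 0.36, the protease Ctss had 0.90 ± 0.60, and the signalling adaptor Tyrobp had 0.56 ± 0.33. The 5 negative members included Cd14 at -0.52 and C1qb at -0.49, and the median of the list was 0.12. The list mean was 0.18 on replicate 2, 0.29 on replicate 3 and 0.20 on replicate 4, with 0.0070 on replicate 1. Its adjusted p from camera was 0.107 without replicate 3 and 0.124 without replicate 4.

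None of the ribosomal protein genes reached an unadjusted p under 0.05. Rpl41 had 0.37 ± 0.28 (SD, n = 3), Rps3a1 had 0.41 ± 0.39, Rpl37a had 0.41 ± 0.44 and Rpl27 had 0.39 ± 0.49. The list mean rested on replicate 3, at 0.52, against 0.07 on replicate 2 and -0.12 on replicate 4, and replicate 1 had 0.39. Without replicate 3 the list took the opposite sign, with an adjusted p of 0.917 from camera.

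**Figure D2:**
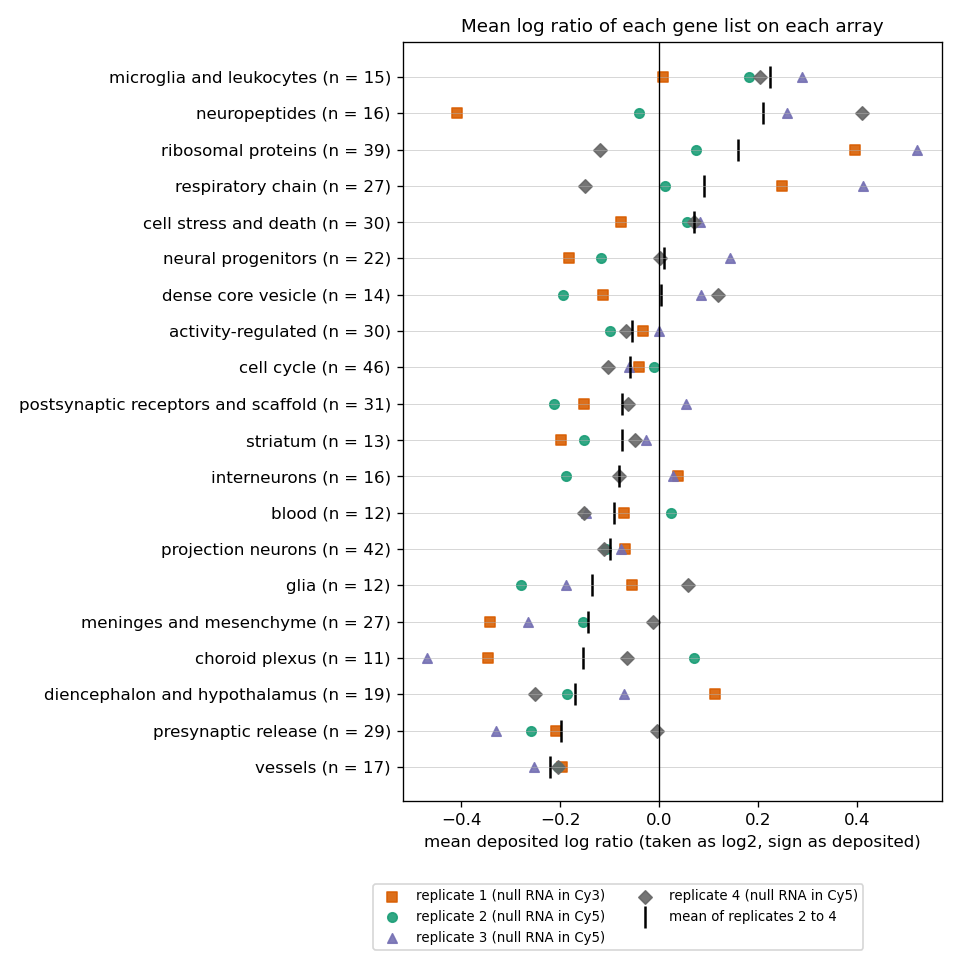
Mean deposited log ratio, taken as log2, of the measured members of each of 20 gene lists on each of the 4 arrays (markers) and over replicates 2 to 4 (bars), with the number of members in brackets. The ribosomal protein list lies at 0.52 on replicate 3 and at -0.12 on replicate 4, and the vessel list lies between -0.25 and -0.20 on every array.

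The vessel list had the mean furthest below 0, at -0.22, with 12 of 17 members negative and 5 of them at an unadjusted p under 0.05. The endothelial transcription factors Sox17 and Sox18 had -1.41 ± 0.86 (SD, n = 3) and -0.48 ± 0.14, the efflux pump Abcb1a had -0.37 ± 0.02, and Cdh5, the cadherin of endothelial junctions, had -0.41 ± 0.24. The list's adjusted p from limma was 0.0511 with camera, 0.652 with an estimated correlation and 0.0384 with fry, which asks whether the members move together in a single direction. Median-centring each array took vessels past the camera threshold, at 0.0488, as did leaving out replicate 3, at 0.0435. Vessels did not pass camera without replicate 2, at 0.0676, or without replicate 4, at 0.226. On 4 arrays the camera value was 0.503 with replicate 1 turned and 0.0145 with it as deposited. Among projection neuron genes, 33 of 42 were negative with a mean of -0.10, and the adjusted p was 0.102 with camera, 0.0384 with fry and 0.652 for camera with an estimated correlation. Cux1, a factor of upper cortical layers, had -0.49 ± 0.22, Neurod2 had -0.44 ± 0.25, Ncam1, a neural adhesion molecule, had -0.34 ± 0.13 at the probe with the smallest p and -0.21 over its probes, and the microtubule-associated protein Dcx had 0.40 ± 0.21.

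Other neuronal and developmental lists did not pass the camera test of limma. The activity-regulated list, which holds immediate early genes, had 8 of 30 members positive and a mean of -0.06, with an adjusted p of 0.635. These 30 were the measured ones of 44, and Fos, Arc and Jun were not among them. Tiparp, a poly-ADP-ribose polymerase family member, was its only gene at an unadjusted p under 0.05, at 0.74 ± 0.14 (SD, n = 3), and Ier2 and Pim1 had -0.30 ± 0.15 and -0.65 ± 0.95. Nfil3 had -0.32 ± 0.10 at the probe with the smallest p and -0.18 over its probes. Postsynaptic genes had 14 of 31 positive and an adjusted p of 0.619, with the kainate receptor subunit Grik5 at -0.45 ± 0.21 and the nicotinic receptor subunit Chrna7 at 0.37 ± 0.12. Camk2b, a subunit of calcium/calmodulin-dependent kinase, had -0.44 ± 0.36 at the probe with the smallest p and -0.19 over its probes, which the list test used. Dense core vesicle genes had 8 of 14 positive and an adjusted p of 0.990, with Pcsk1n at -0.52 ± 0.27, Scg3 at 0.46 ± 0.22 and the calcium sensor Syt7 at -0.60 ± 0.46. Interneuron genes had 6 of 16 positive and an adjusted p of 0.561, with the GABA-synthesising enzyme Gad2 at 0.72 ± 0.22, the calcium-binding protein Calb1 at -0.63 ± 0.53 and the transcription factor Lhx6 at -0.35 ± 0.18, or -0.28 over its probes.

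Neural progenitor genes had 11 of 22 positive, and camera gave an adjusted p of 0.961. The endothelin receptor Ednrb had 0.80 ± 0.21 (SD, n = 3), the cortical homeobox factor Emx1 had -0.63 ± 0.37 and the surface protein Prom1 had 0.54 ± 0.36. The list mean was 0.0093 and the median -0.013. Cell cycle genes had 23 of 46 positive and an adjusted p of 0.723 in limma, with the spindle checkpoint kinase Bub1 at 0.50 ± 0.08 and Ccne1, cyclin E1, at -0.44 ± 0.16. Glial genes had 4 of 12 positive and an adjusted p of 0.415, with the gap junction protein Gja1 at -0.56 ± 0.33 and the factor Olig1 at 0.29 ± 0.12. Genes of cell stress and death had 17 of 30 positive and an adjusted p of 0.295. Of these, Hrk, a pro-apoptotic member of the Bcl-2 family, had 0.67 ± 0.06 and Apaf1, the scaffold of the apoptosome, had 0.54 ± 0.13. Respiratory chain genes had 18 of 27 positive and an adjusted p of 0.278, with the cytochrome oxidase subunit Cox5b at 0.45 ± 0.06. That list had an adjusted p of 0.0315 without replicate 4, took the opposite sign without replicate 3 at 0.539, and had an adjusted p = 0.813 with an estimated correlation.

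Markers of other tissues did not pass the camera test on replicates 2 to 4 together either. Blood genes had 6 of 12 positive, an adjusted p of 0.561 in limma, and 1 member past the threshold when adjusted over the list alone, the embryonic globin Hba-x at -0.74 ± 0.17 (SD, n = 3). The red cell anion exchanger Slc4a1 had -0.49 ± 0.15. Genes of meninges and mesenchyme had 11 of 27 positive, an adjusted p of 0.561, and 1 member, Ptgds, past the threshold when adjusted over the list alone. The collagen gene Col6a1 had -2.20 ± 1.46, another collagen gene, Col5a1, had 0.68 ± 0.56, and the forkhead factor Foxc1 had -0.38 ± 0.12. Choroid plexus genes had 5 of 11 positive, an adjusted p of 0.910, and 1 member past the threshold when adjusted over the list alone. This member, the tight junction protein Cldn2, had 1.27 ± 0.71 and the anti-ageing factor Kl had 0.62 ± 0.43, whereas Ttr, the transthyretin abundant in that tissue, had -0.68 ± 0.53. Striatal genes had 7 of 13 positive and an adjusted p of 0.944, with the G protein subunit Gng7 at 0.39 ± 0.12 and the retinoic acid receptor Rarb at -0.46 ± 0.31. Genes of diencephalon and hypothalamus had 15 of 19 negative, a mean of -0.17 and an adjusted p of 0.0561, with the thalamic factor Tcf7l2 at -0.43 ± 0.14 and the hypothalamic factor Sim1 at -0.61 ± 0.64. That list passed camera without replicate 3, with an adjusted p of 0.0435, and with arrays centred and set to a common scale, at 0.0350. It did not pass without replicate 2, at 0.0884, or without replicate 4, at 0.407. The list had an adjusted p = 0.652 with an estimated correlation and 0.337 with fry.

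The 20 lists held 456 genes, 11 of them in several lists, and 55 members had an unadjusted p under 0.05. The 55 were counted after averaging probes by gene. Among all single probes tested, 553 of 5720 had such a p. After averaging by gene, with unnamed probes kept, that number was 536. When adjusted over the list alone, with no adjustment for the number of lists, 5 members passed. When adjusted over all genes tested with limma, 0 passed.

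All 4 arrays together give a different ranking for each assumed sign of replicate 1. If the ratio was channel 2 over channel 1, replicate 1 has to be turned. With replicate 1 turned, Cdc42ep5 had a mean of 1.06 ± 0.30 (SD, n = 4), Gngt1, a transducin subunit of rod cells, had 0.98 ± 0.32, and Hrk had 0.69 ± 0.06. Cep295nl and the vomeronasal receptor Vmn2r30 had 1.01 ± 0.40 and 0.63 ± 0.02. On the negative side were Car8 at -1.12 ± 0.46, Esyt1, a tether between the endoplasmic reticulum and the plasma membrane, at -0.79 ± 0.20, Abhd1, an alpha/beta hydrolase, at -0.74 ± 0.06, Cat, catalase, at -0.67 ± 0.07, and the ETS factor Etv2 at -0.65 ± 0.18.

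Of 5687 probes in that fit, 0 had an adjusted p under 0.05 with limma, 480 had an unadjusted p under 0.05 where chance with no effect gives 284, and the 10 genes named had an adjusted p of 0.371. A single sign on all 4 arrays was seen for 18.1% of probes, against 12.5% by chance. Both chance rates take the arrays as independent, though they share a pool. Neuropeptides were the only list past the camera threshold, with an adjusted p of 0.00323 and an adjusted p = 0.734 with an estimated correlation. Without replicate 2 the number at an unadjusted p under 0.05 was 269.

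If the ratio was null over control on every array, replicate 1 stays as deposited. Then 2 probes passed the adjusted threshold with limma, the unnamed probe 2965 at 2.68 ± 0.37 (SD, n = 4), or 6.39-fold, with an adjusted p of 0.00345, and the unnamed probe 2996 at -1.69 ± 0.33, or 3.23-fold, with an adjusted p of 0.0300. Each had its sign on 4 of 4 arrays. The named genes with the smallest p did not pass. They were Lyz1 at 0.76 ± 0.04, B2m, the light chain of MHC class I, at 0.72 ± 0.14, the kinases Clk4 and Mast4 at 0.68 ± 0.24 and 0.59 ± 0.10, and Mtcp1 at 0.65 ± 0.24. Ptgds had -1.49 ± 0.57, Sypl2 had -1.17 ± 0.52, the cell cycle factor E2f3 had -0.98 ± 0.33, the Wnt co-receptor Lrp6 had -0.75 ± 0.21 and Aass had -0.72 ± 0.27. Their adjusted p ranged from 0.372 for Ptgds to 0.663 for Aass, Mast4, Clk4 and Mtcp1 with limma.

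At an unadjusted p under 0.05, that fit listed 405 probes, and 15.5% of probes had a single sign on all 4 arrays. Ribosomal proteins (adjusted p of 2.33e-06), presynaptic release (0.00154), vessels (0.0145) and the respiratory chain (0.0479) passed with camera. With an estimated correlation none did, with an adjusted p = 0.651 for ribosomal proteins and the respiratory chain and an adjusted p = 0.562 for presynaptic release and vessels. That form of camera again had few degrees of freedom.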

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

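All tests of explanations in this part were chosen after the result was seen. Over 129 values tested across the 4 arrays (array summaries, list means and named genes), 12 had a single array far from the other 3, with a gap to the nearest other value above Dixon's 95% limit for 4 values, where a chance rate of 5% gives 6.45. Of these, 10 were on replicate 1, the array with the other dye orientation and the other day in its source name. Most of the genes had been selected for a small spread on replicates 2 to 4, or for a shared sign after replicate 1 was turned, and either selection favours such gaps.

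Replicate 1 stood apart for Smcp at -0.30 (others 1.33 to 1.64), Enc1 at -0.41 (0.74 to 0.95), Hrk at -0.74 (0.60 to 0.72), Vmn2r30 at -0.60 (0.63 to 0.65) and Chrna7 at -1.002 (0.24 to 0.47). It lay above the others for Abhd1 at 0.76 (others -0.79 to -0.65), Cat at 0.70 (-0.73 to -0.57), Abcb1a at 0.065 (-0.39 to -0.35) and Sdha, a subunit of succinate dehydrogenase, at 0.26 (-0.28 to -0.21). The mean of the list of cell stress and death was -0.077 on replicate 1 and 0.06 to 0.08 on the others. Replicate 3 stood apart for the choroid plexus list member Msx1, a homeobox factor, at -6.27 (others -1.25 to -0.43), and for the mean of the vessel list, at -0.253 (-0.205 to -0.196).

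The 553 probes at an unadjusted p under 0.05 on replicates 2 to 4 exceed the 286 of chance, but the excess rests on replicate 2, since replicates 3 and 4 alone gave 236 where chance gives 289. Of the 4 sign patterns of these arrays, 1 gave as many, the real one, and the highest other gave 254; 4 patterns are too few for a share under 5%. A dye effect or a deviation of the pool carried alike by every array, as the only component they share, would give each pair of arrays a like covariance. That of replicates 3 and 4 was -0.000482 (95% bootstrap interval over probes -0.0097 to 0.0089), below 0.0587 (0.0470 to 0.0707) for replicates 2 and 3 and 0.0344 (0.0269 to 0.0429) for replicates 2 and 4, which argues against such an effect and equally against an effect of genotype carried alike. Unequal effects of dye, pool or genotype, components that offset each other, and a property of replicate 2 stay open and untested.

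With replicate 1 as deposited, 2 probes passed the threshold. Of the 8 sign patterns of the 4 arrays, 1 gave as many, the pattern as deposited, and the highest other gave 1; 8 patterns are too few for a share under 5%. If the ratio was channel 2 over channel 1 on each array, both probes would carry a dye effect, since their sign then followed the dye and not the genotype. If it was null over control, they would carry a difference between null and pool. The numerator is not given in the sources used here, and Xist and Uty do not settle it. Their signs on replicate 1 are those of replicate 4 as deposited and those of replicates 2 and 3 once turned. By size, Xist on replicate 1 would once turned lie 4.81 above its mean of 1.22 on replicates 2 and 3. Uty goes the other way, since its 1.496 on replicate 1 is nearer in size to -1.61 and -1.12 on replicates 2 and 3 than to 0.35 on replicate 4. Single values of these genes on 1 array leave the numerator open.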

How the results depend on the processing

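All alternatives in this part were planned. Of 1291 alternative values for single genes and probes and for the 4 called lists, 1246 kept their sign and their side of the threshold, 21 lost a call with the same sign, 7 gained one and 17 changed sign, of which 3 also lost a call, so that 24 calls were lost, all in the lists. No single gene or probe was called in the main fits, so only the 4 lists had a call to lose. Genes picked for a single sign on every array of a fit cannot change sign when an array of that fit is left out or weighted. Those kept signs were fixed in advance. Of 11 alternatives each, the call was kept in 5 for neuropeptides, 6 for presynaptic release, 3 for microglia and leukocytes and 6 for ribosomal proteins. The 11 alternatives include camera with an estimated correlation, which had few degrees of freedom, and fry, which asks another question. Of 176 alternative values for the other 16 lists, 142 kept both sign and side, 13 gained a call (in 5 lists) and 21 changed sign (in 8 lists, with 0 past the threshold at the new sign). For replicates 2 to 4, the number past the adjusted threshold was 1 with a robust variance prior (probe 2965), 3 with array weights and 1 at an adjusted p under 0.1, and it stayed at 0 without each replicate in turn. The number at an unadjusted p under 0.05 was 1067 with array weights and ranged from 236 (without replicate 2) to 621 without each replicate in turn. For 4 arrays with replicate 1 turned, 0 probes passed. With replicate 1 as deposited 2 passed, and with a dye term 1 passed, Tal1 (mean 2.40) with replicate 1 turned and probe 2965 (2.78) with it as deposited. Leaving out each replicate gave 269 (without replicate 2) to 553 at an unadjusted p under 0.05. The lists past the threshold numbered 4 with camera, 1 on 4 arrays with replicate 1 turned, 1 with a dye term added to that fit, 0 with an estimated correlation, 2 with fry, and 2 (without replicate 3) to 4 without each replicate. The 2 with fry were vessels and projection neurons, and none of the 4 called lists was among them. Without replicate 3, 0 of the 4 called lists passed, and those that did were vessels and the diencephalon. The number rose to 5 with median centring (vessels added), 6 with a common scale as well (vessels and diencephalon added) and 5 with a dye term and replicate 1 as deposited (presynaptic release, ribosomal proteins, respiratory chain, vessels and meninges). With a dye term and replicate 1 turned, means changed sign to -0.20 for probe 2965, -0.033 for Lyz1, -0.14 for B2m, -0.077 for Mast4, 0.25 for Ptgds, 0.19 for E2f3 and 0.0059 for Lrp6. With a dye term and replicate 1 as deposited, they changed to -0.11 for Cdc42ep5, -0.057 for Gngt1, -0.037 for Hrk, 0.013 for Abhd1, 0.12 for Esyt1, 0.025 for Cat and 0.016 for Etv2. Apart from probe 2965, these genes were picked in the fit with the opposite sign of replicate 1. Probe 2965 was picked on replicates 2 to 4 alone, and Ptgds, Cdc42ep5, Lyz1 and Hrk were picked on those arrays too. A dye term gives replicate 1 as much weight as the other 3 together. Neuropeptides changed sign with a dye term and replicate 1 as deposited (adjusted p 0.573, range over alternatives 0.00147 to 0.813), and ribosomal proteins with a dye term and replicate 1 turned (0.134) and without replicate 3 (0.917), with a range of 6.69e-05 to 0.917 without each replicate. The cause of the sign changes and of the other changes was not tested. No paired analysis was possible because the control was a single pool. Signal over background, which the log ratios do not carry, limits what can be said of weak probes.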

Other observations

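The test of Xist and of Y-linked genes in this part was chosen after the result was seen, as were the genes of the next paragraph.

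The 3 transcription factor genes Sox3, Pou3f2 and Pou3f3, which are outside the lists, had a negative log ratio on 4 of 4 arrays as deposited. On replicates 2 to 4, Sox3, a SoxB1 factor of neural progenitors, had -0.62 ± 0.21 (SD, n = 3), Pou3f2, the POU factor Brn2, had -0.52 ± 0.10 and its relative Pou3f3 had -0.51 ± 0.31. On replicate 1 they had -0.54, -0.83 and -1.11. None passed, with an adjusted p of 0.454 for Sox3, 0.457 for Pou3f2 and 0.473 for Pou3f3 in limma. They were picked for their shared sign, and 7.74% of all probes were also negative on 4 of 4 arrays, against 6.25% by chance for independent arrays.

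Xist, the X-inactivation RNA, differed widely between arrays, with -6.03 on replicate 1, 0.90 on replicate 2, 1.54 on replicate 3 and -3.16 on replicate 4. The Y-linked gene Uty had the opposite sign on 4 of 4 arrays, at 1.496, -1.61, -1.12 and 0.35. The median of the 4 Y-linked genes Uty, Kdm5d, Eif2s3y and Zfy1 had the sign opposite to Xist on 3 of 4 arrays, at 0.67, -0.45, 0.10 and 0.20, so null embryos of different sex against a single pool may account for the spread, without this test showing it. Noise of single values was not tested. The sex of the embryos is not in the labels, and no biological explanation beside it was tested.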
